A study of Arabidopsis thaliana with 49 samples.

How the data were processed

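Libraries came from Arabidopsis thaliana plants carrying 1 of 4 multigene transgene constructs. Per the labels' protocols, small RNA and RNA-seq libraries were made with Illumina TruSeq kits from total RNA of developing green siliques, and methylC-seq libraries, in which bisulfite conversion marks unmethylated cytosines, from genomic DNA of inflorescences. Sequencing was on an Illumina HiSeq instrument, per the labels.

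The values used were counts of reads per library, deposited by the authors as a single table with a line for each of the 49 libraries. Per the file headers, the counts are total sequenced reads, genome-matched reads that exclude transfer, ribosomal, small nuclear and small nucleolar RNA, distinct genome-matched reads, and reads matched to those structural RNAs. For methylC-seq the deposited counts also include reads matched to the chloroplast and the mitochondrial genome, and structural RNA reads are not listed. The authors also deposited the longest and shortest read length of each library in nt, an other kind of value that served here only to describe the libraries and to split them. The counts were not normalized. The genome build was TAIR10 per the submitters' processing notes. The aligner, the mismatches allowed, the treatment of reads with several matches, the adapter trimming and whether the reference held the transgene sequences are not given in the sources used here. Neither is a definition of distinct reads, so the distinct share is the authors' distinct count as a percent of their genome-matched count.

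From these counts, the genome-matched share and the structural RNA share were computed as percent of total reads, and the distinct share as percent of genome-matched reads. The unplaced share is the percent of total reads in neither the genome-matched nor the structural RNA count. Library size was tested as log10 of total reads. Because each library gives a few totals and no values per gene, no model across genes was fitted. The largest 95% Wilson interval of any share was ± 0.0957 percentage points, and it covers counting error only, since PCR copies are not independent molecules. It belongs to a distinct share. A count of distinct reads is not a plain draw from the matched reads, so for that share the interval is nominal only. All value columns of the table were mapped to labelled samples.

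Groups followed the labels: assay, construct and, for the RNA assays, the generation of the seeds in the siliques, named T2, T3 or T4. An event is an independent insertion of a construct, and plants of 1 event are siblings, so p-values over plants measure the spread among related plants. Group means were compared by exact two-sided permutation tests on the absolute difference, with Benjamini-Hochberg adjustment over 65 tests, of which 30 could reach p below 0.05 given their group sizes. Outside this adjustment are the alternatives and the tests of the closing section, among them 5 methylC-seq measures of DAS588 and the unplaced share of DAS525 against DAS454, which were chosen after the values were seen. Small RNA and RNA-seq libraries of T4 seeds of 14 plants were compared by a permutation test with 100000 resamples. This test took the libraries as independent. The plant number pairs them, because both came from the same plant, and a test with the plant as a block was run as an alternative. The deviations of paired libraries from the mean of their construct within each assay correlated at -0.27 for the genome-matched share and 0.37 for the distinct share. For correlations, 23 relations were computed with permutation p-values and adjusted together. The exact permutation test between groups was tested on separated and on simulated values. The routines for the resampled, blocked and correlation p-values were not.

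The groups, the tests of library size, genome-matched share and distinct share and the alternatives for them were chosen before the data were examined. The alternatives were medians in place of means, event means in place of plants, another scale, each library left out in turn, DAS525 against each other construct alone, and the plant as a block. Added after the values were seen were the structural RNA, unplaced and organelle shares, the comparison of generations and the subsets by longest read. So were a denominator without structural RNA reads, the relation of distinct share to matched reads and an adjustment of that share for total reads. The plan counted every methylC-seq library separately, and the merging of identical libraries into a single sample was decided after the values were seen.

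The rule for named items was that every library and every sequence class of the table may be named, since no gene-level file was listed. A share of reads matched to the transgenes, and its correlation between small RNA and RNA-seq, had been planned; transgene-matched reads, gene-level expression and methylation levels were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.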

Results

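The series addresses whether the base composition of coding sequences affects small RNA-mediated silencing of transgenes. All constructs carry PFA1, PFA2, PFA3 and HetI. In DAS454 and DAS588 all 4 coding sequences are canola-biased, in DAS496 the PFA3 sequence is microalgal, and in DAS525 PFA1, PFA2 and PFA3 are microalgal. The 49 libraries comprise 21 small RNA, 21 RNA-seq and 7 methylC-seq libraries. The generation in the labels is that of the seeds in the sampled siliques. Small RNA and RNA-seq libraries were each made from T4 seeds of 6 DAS454, 6 DAS588 and 2 DAS525 plants, from T3 seeds of 2 DAS454 and 3 DAS496 events, and from 1 DAS454 and 1 DAS496 sample of T2 seeds. Libraries are called T2, T3 or T4 after these seeds, and plants are named by the number of the plant that bore them. The methylC-seq libraries came from 2 DAS454, 3 DAS588 and 2 DAS525 plants.

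Small RNA libraries held between 19883111 and 89657040 reads, RNA-seq libraries between 16228763 and 32035964 reads, and methylC-seq libraries between 83798885 and 263494112 reads. At these depths the counting error of the shares of total reads was far below the spread between plants. The longest read of T4 small RNA libraries was 34 nt throughout. It was 31 nt in the T2 small RNA libraries and in those of DAS496 events 023 and 038, and 34 nt in the other T3 ones. The T4 RNA-seq libraries had a longest read of 45 nt in all 6 DAS454 plants and of 50 nt in all 6 DAS588 plants.

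Structural RNA, that is transfer, ribosomal, small nuclear and small nucleolar RNA, made up most of the small RNA reads of T4 siliques in every construct. Its share was 69.2% ± 6.16 (SD, n = 6) in DAS454, 68.2% ± 5.08 (SD, n = 6) in DAS588 and 68.7% ± 7.76 (SD, n = 2) in DAS525. Genome-matched reads outside these classes, which include microRNAs and small interfering RNAs, made up 19.1% ± 5.26 (SD, n = 6), 24.2% ± 5.06 (SD, n = 6) and 19.4% ± 6.54 (SD, n = 2) in the same order.

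**Figure D1:**
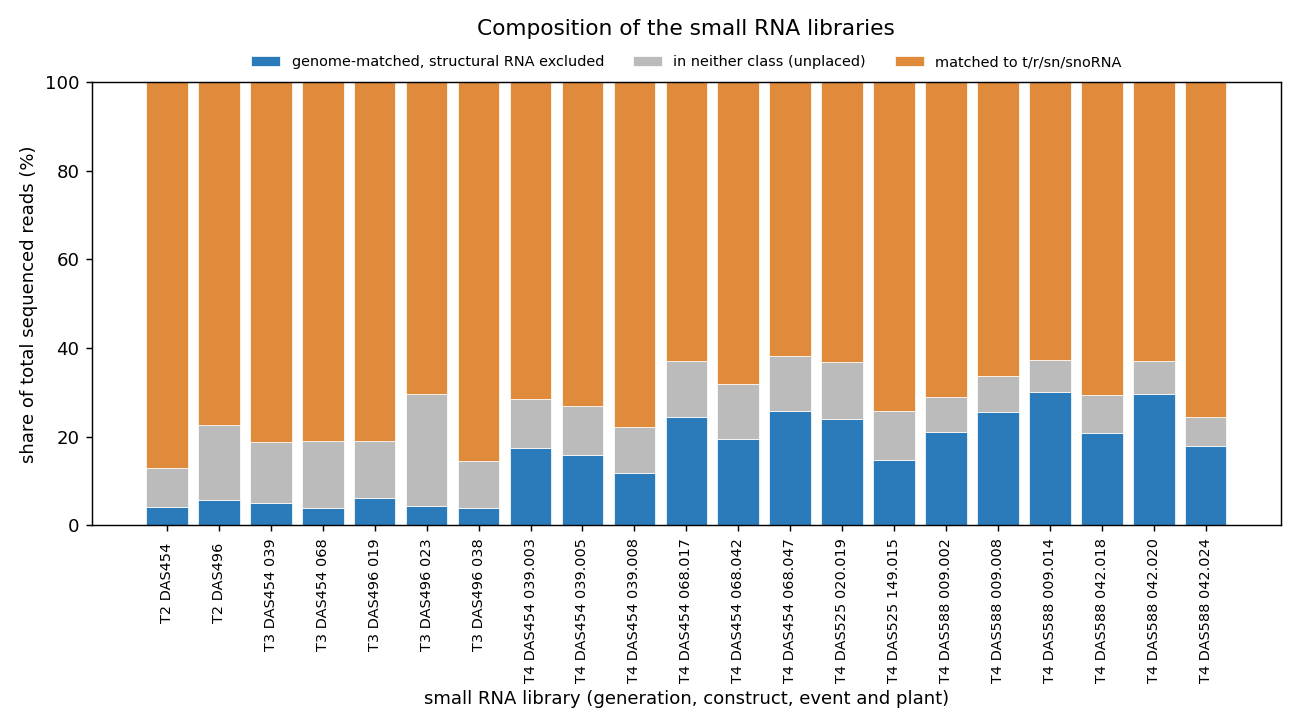
Composition of each small RNA library as a percent of total reads on the vertical axis, with 1 stacked bar per library named by generation, construct, event and plant. Blue marks genome-matched reads outside structural RNA, grey reads in neither class and orange structural RNA; the blue share is at most 6.27% in the T2 and T3 libraries and at least 11.8% in the T4 libraries.

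Microalgal and canola-biased PFA coding sequences were compared through DAS525 against DAS454 and DAS588 together. The genome-matched share of small RNA in DAS525 was 14.7% in plant 015 and 23.99% in plant 019, on either side of the mean of 21.7% ± 5.58 (SD, n = 12) in the canola-biased plants. The difference of -2.29 points (SE 4.90) was smaller than the spread between plants (exact p = 0.604, adjusted p = 0.893). The distinct share was 34.8% ± 3.34 (SD, n = 2) against 33.2% ± 7.26 (SD, n = 12), a difference of 1.58 points within the spread (exact p = 0.780). The direction of both differences rests on 1 library and on the construct compared. Without plant 015 they were 2.33 points for the genome-matched share and -0.778 points for the distinct share. Against DAS454 alone they were 0.225 points (exact p = 1) and -2.74 points (exact p = 0.5), and against DAS588 alone -4.81 points and 5.91 points (exact p = 0.357 each). As a percent of the reads that were not structural RNA, the genome-matched share was 61.1% ± 5.74 (SD, n = 2) in DAS525, 61.3% ± 5.06 (SD, n = 6) in DAS454 and 75.5% ± 4.14 (SD, n = 6) in DAS588.

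DAS588 and DAS454, which share the same coding sequence design, differed in the reads that were in neither class. The unplaced share was 7.65% ± 0.744 (SD, n = 6) in DAS588 and 11.7% ± 0.984 (SD, n = 6) in DAS454, with no overlap. The difference of -4.04 points (SE 0.504) gave exact p = 0.00216, the smallest this design allows, and adjusted p = 0.141. DAS588 plants also had a lower distinct share, 28.8% ± 6.78 against 37.5% ± 5.01 (SD, n = 6 each), a difference of -8.66 points (exact p = 0.0303, adjusted p = 0.281). This call was lost in 5 of 12 omissions of a single library, those of DAS588 plants 014 and 020 and DAS454 plants 003, 005 and 008, with differences of -8.39 to -6.59 points (exact p from 0.0584 to 0.0671). Event means, 2 against 2, cannot give p below 0.333 for any measure. Genome-matched shares differed by 5.03 points (SE 2.98), within the spread (exact p = 0.123). Taken as a percent of the reads that were not structural RNA, they differed by 14.2 points (exact p = 0.00216). With this denominator, genome-matched and unplaced reads make up the whole. The 14.2 points thus restate the unplaced difference and are not separate evidence.

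**Figure D2:**
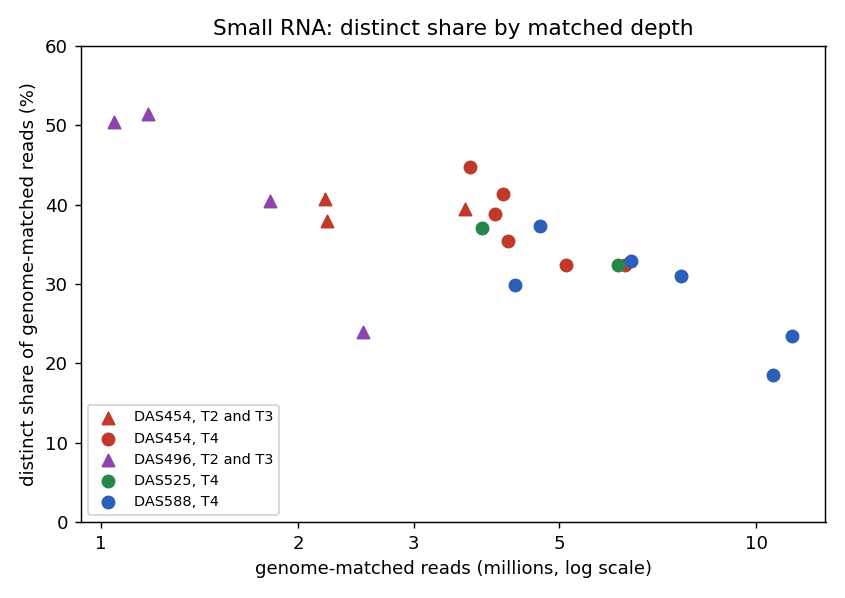
Distinct share of genome-matched small RNA reads in percent (vertical axis) by the number of genome-matched reads on a log scale (horizontal axis), which is also the denominator of the share, with 1 point per library, coloured by construct, circles for T4 and triangles for T2 and T3. The lowest T4 value is 18.5% in DAS588 plant 014 and the highest is 44.7% in DAS454 plant 008.

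The events of DAS454 separated in their small RNA libraries. Event 068 had a higher genome-matched share than event 039, 23.2% ± 3.30 against 15.1% ± 2.97 (SD, n = 3 each), and a lower structural RNA share, 64.2% ± 3.31 against 74.1% ± 3.35. Its distinct share was lower, 33.4% ± 1.74 against 41.6% ± 2.94, and its unplaced share higher, 12.6% ± 0.0925 against 10.8% ± 0.390. In all 4 measures the 3 plants of an event did not overlap with those of the other, which gives exact p = 0.1, the smallest that 3 plants against 3 allow and the share of such separations that chance gives (10%). The genome-matched, structural and unplaced shares add up to the whole library and are not separate evidence. The distinct share is tied to them through its denominator, the genome-matched reads. These numbered 4172780 to 6302707 in event 068 and 3654923 to 4108078 in event 039. Within DAS454 at T4 the distinct share fell with that number (r = -0.84, n = 6). As a percent of the reads that were not structural RNA, the genome-matched shares of the events overlapped (difference 6.80 points, exact p = 0.2). The DAS588 events 042 and 009 did not separate, with genome-matched shares of 22.8% ± 6.11 and 25.6% ± 4.58 (SD, n = 3 each; exact p = 0.5).

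Small RNA libraries of DAS454, the construct sampled in all generations, contained several times more genome-matched reads per total reads at T4 than at T2 and T3. The genome-matched share was 19.1% ± 5.26 (SD, n = 6) at T4 and 4.42% ± 0.556 (SD, n = 3) at T2 and T3, a 4.33-fold difference of 14.7 points (SE 2.17). The structural RNA share was 69.2% ± 6.16 at T4 and 83.0% ± 3.42 at T2 and T3. Neither measure overlapped between the generations (exact p = 0.0119, the smallest possible, and exact p = 0.0238; adjusted p = 0.246 and 0.258). The T2 and T3 libraries were also larger, 43496250 to 89657040 reads against 19883111 to 30988928 (exact p = 0.0119). The genome-matched call was lost with medians (14.3 points, exact p = 0.0714) and with event means, which cannot give p below 0.1, and as a percent of the reads that were not structural RNA the difference was 34.5 points (exact p = 0.0119). The structural RNA call was lost with medians (-11.6 points, exact p = 0.119), with event means, without the T2 library (-11.9 points, exact p = 0.0714) and without T4 plant 042 (-13.7 points, exact p = 0.0536). Set within the events, T4 minus T3 was 10.04 points in event 039 and 19.2 points in event 068 for the genome-matched share, and -7.19 and -16.6 points for the structural RNA share. Library size on the log10 scale differed by -0.22 and -0.61 in the same order (exact p = 0.25 each, the smallest possible within an event).

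DAS496 and DAS454 were compared at T3, where only PFA3 differs in design and 3 libraries against 2 cannot give p below 0.1. Genome-matched small RNA shares were 4.88% ± 1.22 (SD, n = 3) and 4.53% ± 0.740 (SD, n = 2), within the spread (exact p = 0.9), and the direction turned with medians (-0.146 points), without DAS496 event 019 (-0.343 points) and without DAS454 event 068 (-0.170 points). The DAS496 libraries were smaller, with 23931663 to 29629094 reads against 43496250 and 89657040 (exact p = 0.1). Their longest read was 31 nt in events 023 and 038 and 34 nt in event 019, against 34 nt in DAS454. Construct and read length thus partly coincide. In RNA-seq the genome-matched share was 71.0% ± 7.21 (SD, n = 3) in DAS496 and 80.5% ± 2.25 (SD, n = 2) in DAS454 (exact p = 0.2). This difference of -9.56 points was -5.41 points without DAS496 event 023, which had 62.7%, and -6.01 points with medians.

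In RNA-seq of T4 siliques, most reads matched the genome in each construct, 75.7% ± 2.05 (SD, n = 6) in DAS454, 77.4% ± 2.31 (SD, n = 6) in DAS588 and 77.3% ± 0.848 (SD, n = 2) in DAS525. The DAS588 and DAS454 values differed by 1.69 points (exact p = 0.206), by 2.61 points without DAS588 plant 014 (exact p = 0.0281), and by 2.76 points as a percent of the reads that were not structural RNA (exact p = 0.0152). The 2.76 points restate the unplaced difference given next and are not separate evidence. DAS588 had a higher distinct share, 37.3% ± 2.55 against 32.0% ± 3.37 (SD, n = 6 each; exact p = 0.0216, adjusted p = 0.258), and a lower unplaced share, 20.5% ± 0.187 against 23.5% ± 1.80 (exact p = 0.0152, adjusted p = 0.246). Longest read and construct coincide in these libraries, so the construct and the read length cannot be told apart. The distinct share in DAS525 was 28.2% ± 1.66 (SD, n = 2), a difference of -6.43 points from the 12 canola-biased plants (exact p = 0.0879). It was -3.76 points against DAS454 alone (exact p = 0.214) and -9.10 points against DAS588 alone (exact p = 0.0357), and -2.59 points among libraries of 45 nt and -10.3 points among those of 50 nt, with 1 DAS525 library in each. It passed the threshold with medians (-7.30 points, exact p = 0.0330), without DAS454 plant 042 or 047 (exact p = 0.0256) or DAS588 plant 002 (exact p = 0.0385).

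**Figure D3:**
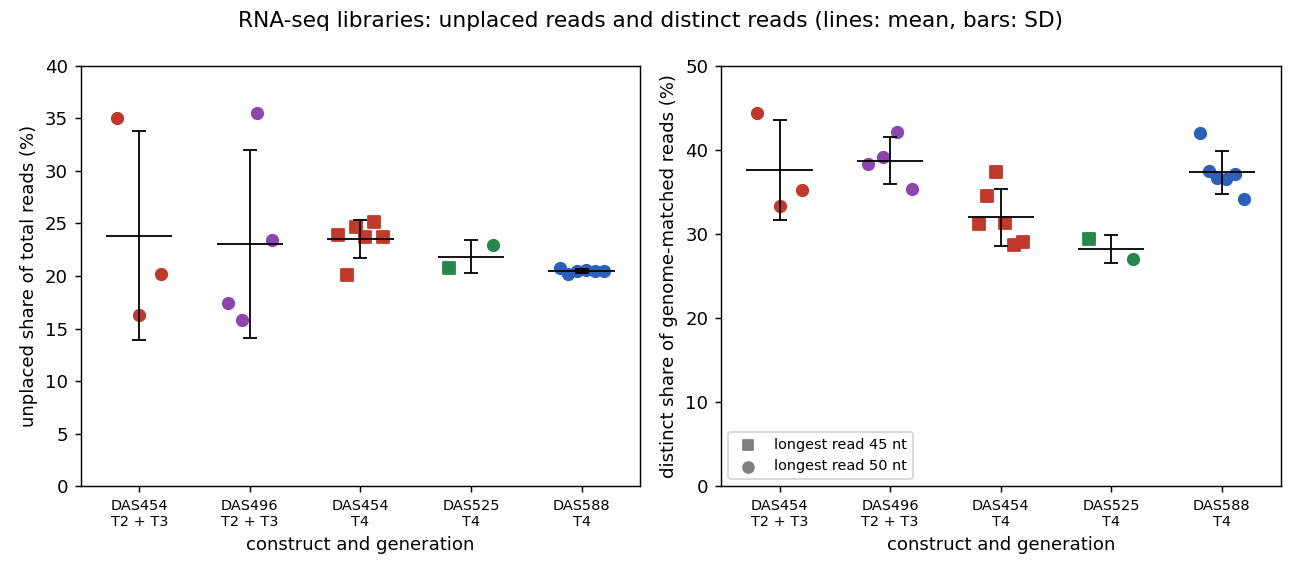
Unplaced share of total reads (left) and distinct share of genome-matched reads (right) of the RNA-seq libraries, in percent, by construct and generation, with 1 point per library (squares for a longest read of 45 nt, circles for 50 nt), lines for means and bars for SD. At T4 the unplaced share lies between 20.2% and 20.8% in DAS588 and between 20.1% and 25.2% in DAS454.

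The methylC-seq libraries of DAS588 plants 008 and 020 were listed with the same value in all 5 counts, and were counted as 1 sample. This merging was decided after the values were seen, whereas the plan had counted them separately. No other of the 441 pairs of libraries within an assay shared a count. DAS525 libraries were smaller, 83798885 and 89209387 reads against at least 169932048 in the others (exact p = 0.0667, the smallest possible after the merging). With the identical libraries counted separately, as planned, exact p was 0.0476, again the smallest possible. The genome-matched share was 34.3% in DAS454 plant 047 and between 60.9% and 68.8% in the other libraries. The distinct share was 19.1% in DAS525 plant 015 and 58.6% in plant 019.

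Both RNA assays were made from T4 seeds of the same 14 plants. Structural RNA took 68.7% ± 5.42 of small RNA reads and 1.32% ± 1.61 of RNA-seq reads (SD, n = 14), and genome-matched reads took 21.3% ± 5.51 and 76.7% ± 2.11. Both differences held in 14 of 14 plants, with permutation p = 1.0e-05, the smallest that the resamples can give. This test took the libraries as independent, and with the plant as a block exact p = 0.000122 for each. Both shares are parts of the same reads, so these differences are not separate evidence. The contrast is between assays, and library preparation is part of it. The distinct share, 33.4% ± 6.77 and 33.7% ± 4.37, differed by less than the spread between plants (permutation p = 0.878). This average covers opposite directions, with small RNA higher in 9 of 14 plants. The means in small RNA and RNA-seq were 37.5% and 32.0% in DAS454 (n = 6) and 34.8% and 28.2% in DAS525 (n = 2). In DAS588 they were 28.8% and 37.3% (n = 6). The distinct share can depend on matched depth, which differed between the assays. Genome-matched reads ran from 3654923 to 11316115 in small RNA and from 17217670 to 23593385 in RNA-seq. The longest read differed as well, so the near equality of the means does not show a likeness of the assays. Across plants, the genome-matched shares of both assays were not related (Pearson r = -0.07, permutation p = 0.818; Spearman rho = -0.08, permutation p = 0.785; adjusted p = 0.882; r = -0.07 without the 2 plants farthest from the median). Library size and genome-matched share of small RNA gave r = 0.23 within T4 (permutation p = 0.423) and r = -0.30 within T2 and T3 (exact p = 0.525), and the generations were not pooled for this relation because they form separate clusters.

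Of the 65 exact tests between groups that were adjusted together, 7 gave p below 0.05 and 0 did so after adjustment, the smallest adjusted p being 0.141. That value belongs to a test at exact p = 0.00216, the smallest that any of these designs allows. No test could therefore pass the adjustment on its own, whatever the size of its difference.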

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

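The measures of unplaced and structural RNA share were chosen after the values were seen; the others were chosen earlier. Among 20 combinations of group and measure tested for a library far from its group, 3 had one, and chance gives about 1 in 20. The genome-matched, structural and unplaced shares are parts of the same reads, so the combinations are not independent.

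The RNA-seq library of DAS454 plant 005 stood apart with an unplaced share of 20.1%, against 23.7% to 25.2% in the other DAS454 plants. In DAS588 plant 014 the RNA-seq genome-matched share was 72.8%, against 77.5% to 79.0% in its group. The same library had a structural RNA share of 6.67%, against 0.795% to 1.69%. These entries are not separate, since more structural RNA leaves fewer reads for the other classes. As a percent of the reads that were not structural RNA, the genome-matched share of this library was 78.0%, against 78.8% to 79.6%.

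The RNA-seq difference between DAS496 and DAS454 went opposite ways in T2 and T3, and this change between generations was not tested, since each construct has 1 library at T2. The genome-matched share of DAS496 minus DAS454 was 17.3 points at T2 and -9.56 points at T3. The distinct share differed by -6.14 points at T2 and 4.62 points at T3.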

How the results depend on the processing

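Structural RNA and unplaced shares, the generation comparison, read-length subsets, the denominator without structural RNA and the merging of identical libraries were chosen after the values were seen. Of 531 alternatives over 50 results, 471 kept direction and side of the threshold, 26 lost the threshold, 10 gained it and 24 reversed. Many of the 471 could not change side, because their group sizes allow no p below 0.05. This holds for comparisons of DAS496 with DAS454 and of events within a construct. It also holds for methylC-seq comparisons of constructs, except where identical libraries were counted separately. Such alternatives counted as kept unless the direction turned, so the 471 does not measure robustness. With the plant as a block, the paired difference between small RNA and RNA-seq in genome-matched share was -55.4 points (exact p = 0.000122), and the block changed no call. Transgene-matched alternatives were not run. Counting error of the shares of total reads is small beside the spread between plants, and the number of plants and events limits the tests. The distinct share can also depend on how many reads were matched.

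With event means, designs of 2 events against 2 cannot pass: the small RNA differences of DAS588 from DAS454 were then -8.66 (distinct) and -4.04 points (unplaced), and those in RNA-seq 5.34 and -3.02. For DAS454 T4 against T2 and T3, event means gave -0.387 (log10 size), 14.7 (genome-matched) and -13.9 points (structural), with too few values to pass. Within event 039 these were -0.219, 10.0 and -7.19, and within event 068 -0.605, 19.2 and -16.6, again with too few libraries; the distinct share reversed within event 039 (0.966), for which the cause was not tested. Medians gave 14.3 (exact p = 0.0714) and -11.6 (exact p = 0.119), for which the cause was not tested. Libraries of 34 nt alone gave -11.9 for structural RNA. This subset is the same as leaving out the T2 library, whose longest read was 31 nt.

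Without structural RNA in the denominator, DAS588 exceeded DAS454 in genome-matched share by 14.2 points in small RNA and 2.76 in RNA-seq, both past the threshold. Both values restate the lower unplaced share of DAS588 on another denominator and are not separate evidence. Counting the identical libraries separately, as planned, brought the DAS525 methylC-seq size difference to -0.352 (exact p = 0.0476). Medians moved the T3 DAS496 genome-matched difference to -0.146. For DAS525, against DAS454 alone, small RNA gave 0.0264 (log10 size), 0.225 (genome-matched) and -2.74 (distinct), all reversed. Against DAS588 alone, the genome-matched share gave -0.134 in RNA-seq and -3.13 in methylC-seq, reversed. The RNA-seq distinct difference passed with medians (-7.30) and against DAS588 alone (-9.10), and was -3.76 against DAS454 alone, -2.59 among libraries of 45 nt and -10.3 among those of 50 nt. Libraries of 45 nt alone reversed RNA-seq size (-0.00572), and those of 50 nt alone its genome-matched share (-0.733). The cause was not tested in these cases.

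The correlation of library size and genome-matched share, pooled over generations that form separate clusters in small RNA, is given only to show its dependence. In small RNA the pooled r of -0.45 became -0.23 without the 2 farthest libraries, and was 0.23 within T4 and -0.30 within T2 and T3. In RNA-seq the pooled r of 0.48 (Spearman rho 0.01) reversed to -0.54 without the 2 farthest libraries. It was -0.38 within T4 and 0.66 within T2 and T3, where it became -0.57 without 2 libraries, so its sign rests on those libraries.

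Leaving out each library in turn gave these ranges where a call or direction changed. DAS588 against DAS454 in small RNA: size 0.0645 to 0.119 (highest without DAS588 plant 002), distinct -10.4 to -6.59 (call lost without DAS588 plants 014 or 020 or DAS454 plants 003, 005 or 008), structural -2.47 to 0.741 (reversed without DAS454 plant 008 or DAS588 plants 014 or 020); in RNA-seq, genome-matched 1.27 to 2.61. DAS525 in small RNA: genome-matched -6.92 to 2.33 and distinct -0.778 to 3.95, both by plants 015 and 019; RNA-seq distinct -7.60 to -5.26; methylC-seq genome-matched -1.75 to 9.74 (lowest without DAS454 plant 047) and distinct -26.7 to 12.8 (highest without plant 015). T3 DAS496 genome-matched: -0.343 to 0.877 (reversed without DAS496 event 019 or DAS454 event 068). Without a change of call or direction, the T3 DAS496 difference moved over 1.5 times in RNA-seq genome-matched share (-5.41 without event 023) and in small RNA size (-0.201 without DAS454 event 068, from -0.358). Events: DAS588 small RNA size -0.0157 to 0.125, DAS454 RNA-seq size -0.0493 to 0.0218 and genome-matched -2.36 to 0.579. Generations: structural -15.6 to -11.9 (call lost without the T2 library or plant 042).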

Other observations

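The tests of a shared step, of transgene reads, of the generation pattern and of distinct share adjusted for total reads, the methylC-seq organelle shares and the distinct-share relation were chosen after the values were seen.

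Chloroplast reads made up 0.830% ± 0.114 (SD, n = 2) of the DAS588 methylC-seq libraries and 0.320% ± 0.0716 (SD, n = 4) of the others, a ratio of 2.60 (exact p = 0.0667, the smallest possible). This was 1 of 5 measures compared in a split chosen after the values were seen. The DAS588 values are those of plant 002 of event 009 and those listed alike for plant 008 of event 009 and plant 020 of event 042. They may therefore rest on 1 event. Mitochondrial reads had a ratio of 1.62 (exact p = 0.2), and genome-matched share, distinct share and total reads gave exact p from 0.467 to 0.733. The longest read was 51 nt in DAS588 and 50 nt in the others.

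Distinct share was lower in T4 small RNA libraries with more genome-matched reads (n = 14, Pearson r = -0.87, permutation p = 2.0e-05, adjusted p = 0.00046; Spearman rho = -0.83, permutation p = 0.00037; r = -0.70 without the 2 farthest libraries). It was r = -0.84 within DAS454 (n = 6, exact p = 0.0292) and -0.80 within DAS588 (n = 6, exact p = 0.0653). Genome-matched reads are the denominator of this share, so a negative r is partly built in, and the drop of the DAS588 minus DAS454 difference from -8.66 to -2.01 points (SE 2.77) after adjustment for them decides nothing. Adjusted for log10 total reads instead, the difference was -7.74 points (SE 4.001) with a slope of -10.6 (SE 20.7), too imprecise to decide. Depth and a difference between the constructs both stay open.

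The lower unplaced share of DAS588 small RNA libraries was not accounted for by library size, since the difference adjusted for log10 total reads was -3.52 points (SE 0.450). The RNA-seq libraries of the same plants differed in the same direction, by -3.02 points, so a step shared by the DAS588 libraries cannot be told apart from the construct. Reads from transgenes that the reference lacks also stay open: DAS525 and DAS454, whose PFA sequences differ, were 0.283 points apart (exact p = 0.571), and the sources used here do not say whether the reference held the constructs.

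The generation difference in genome-matched share of small RNA can be set within 1 construct only in DAS454, at 4.33-fold; over all libraries T4 exceeded T2 and T3 by 16.5 points (14 against 7 libraries, permutation p = 2.0e-05), but construct and generation are confounded there. Library size does not account for the low DAS496 values, since 3 DAS496 libraries within the T4 size range reached at most 6.27%, below the lowest T4 value of 11.8%, but within DAS454 size and generation cannot be told apart, since the smallest T2 or T3 library had 43496250 reads and the largest T4 library 30988928. The longest read does not account for the generation difference, since T3 libraries with reads up to 34 nt reached at most 6.27% (5.05% in DAS454). The distribution of read lengths is not among the values used, so a different mix of lengths stays open. Structural RNA reads taking up the libraries do not account for the whole generation difference, but may account for part of it. Within DAS454 the genome-matched share of the remaining reads was 61.3% at T4 and 26.7% at T2 and T3. The ratio of these is smaller than that of the shares of total reads, 19.1% and 4.42%. Over all constructs the generations still did not overlap. T2 and T3 reached at most 33.0% of the remaining reads against 53.2% to 80.8% at T4. A preparation step shared by the T2 and T3 libraries cannot be told apart from generation, as the labels give no date. In RNA-seq, T2 and T3 minus T4 was -2.51 points over all libraries (74.2% against 76.7%). Within DAS454, T4 minus T2 and T3 was 0.726 points (exact p = 0.905). The direction within DAS454 rests on the T2 library at 64.0%. Both T3 libraries, at 79.0% and 82.1%, lay above the T4 mean of 75.7%. The value over all libraries also leans on this T2 library and on DAS496 event 023 at 62.7%.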
